A study of Homo sapiens and Mus musculus with 48 samples.

How the data were processed

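Gene expression (RNA-seq) and chromatin accessibility (ATAC-seq) were measured in 48 samples of mouse and human skin fibroblasts. They formed 24 groups of 2 libraries, A and B, taken from the titles and labels: 4 mouse groups for each assay (JUN or control mice, lipofibroblasts or reticular fibroblasts) and 8 human groups for each assay (normal skin, scar, hypertrophic scar or keloid, unedited or labelled JUN KO, for knockout). Per the labels' protocols, the mouse fibroblasts were isolated by fluorescence-activated sorting at post-operative day 7, and RNA of 10 mice was pooled into 2 biological replicates of 10 wounds each. The human fibroblasts were cultured from 4 patients and their replicates were technical, per the labels, so p-values of the human comparisons measure only the spread between these libraries. ATAC libraries used an average of 50000 cells per replicate, per the labels, and the labels' protocols name an Illumina HiSeq 2500. The JUN mice carry a tetracycline-responsive c-Jun transgene, and the control mice the transactivator alone. For 4 mouse ATAC libraries the title names JUN while the genotype entry names the control line. They were grouped by title.

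All 4 deposited tables hold raw counts per feature: whole-number read counts per gene (mouse RNA), per RefSeq transcript (human RNA) and per region (ATAC), in columns that name the samples. Per the submitters' processing notes, Bowtie2 2.1.0 and DESeq2 were used and the builds mm9 and hg19 are named, without their roles. The read counter, the peak caller and any read shift of the ATAC data are not given in the sources used here. Coordinates are printed as the files give them, with the nearest gene and distance from the same file. No genome sequence was used here, so exon, intron and motif content were not analysed.

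Human transcripts were summed to genes through a RefSeq table (GRCh38.p14, names only), which matched 38546 of 39951 transcripts and 98.9% of the counted reads and gave 24404 genes, 18441 of them with a count. Reads shared between isoforms appear not to be counted in the deposited table. VEGFA, with 18 transcripts listed, had 0 reads, and 328 of 988 genes with 5 or more transcripts had 0 reads in every library, against 3854 of 16919 genes with 1. A CPM value of a gene with several isoforms can therefore be too low. Whether the loss is alike in all groups was not tested. The mouse RNA table lists 26232 Ensembl identifiers (20171 with a count) that the files used here do not pair with names. Jun, Cd36 and gene lists were therefore not looked up in mouse RNA, nor mouse-responsive genes in the human data. Strandedness of the counting is not given in the sources used here, so overlapping genes and near-identical copies are uncertain.

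The ATAC tables hold 268119 human regions (median 466 bp, 200 to 3155) and 127481 mouse regions (median 442 bp, 200 to 4245), 12210 of the latter nearest to an identifier without a gene symbol. Both ATAC tables have 1 line that names no region and holds 0 reads. Columns of samples not mapped numbered 0. For human privacy, XIST, its neighbours and Y-linked features (101 genes and 514 regions) were left out of the tests.

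Counts were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test (glmQLFit, glmQLFTest) after TMM scaling and filterByExpr, with Benjamini-Hochberg adjustment within each comparison at 0.05. This adjusted p is meant wherever one is printed for a gene or region. A single group-means model covered all libraries of a table. The comparison over the 4 skin types summed the technical replicates into 8 libraries and fitted skin type plus genotype. Tested were 16358 mouse genes, 11125 human genes (11727 over the 4 types), 127450 mouse regions and 245690 human regions (259434 over the 4 types). The biological coefficient of variation was 0.470 in mouse RNA, 0.136 in human RNA (0.232 over the 4 types), 0.168 in mouse ATAC and 0.148 in human ATAC (0.257 over the 4 types). Log2 fold changes are given as fitted value ± SE, and levels as mean ± SD in CPM, counts scaled to the TMM-adjusted library size. A fold against a group with 0 counts is a lower bound against a floor of 3 counts over the group. Where a group held 1 to 3 counts only levels are given. Floors cover counting error only.

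The 27 gene lists, fixed before the data were examined like every choice not named otherwise, were the AP-1 family, collagens and matrix, contractile myofibroblast genes, lipid uptake and storage, fatty acid oxidation, cholesterol synthesis, cytokines and chemokines, proteases and inhibitors, TGF-beta and BMP signalling, Wnt signalling, cell cycle, p53 targets, interferon response, hypoxia and glycolysis, stress and immediate early genes, papillary, reticular and pan-fibroblast genes, innate checkpoint ligands, HOX genes, and markers of macrophages and leukocytes, endothelium, keratinocytes, mural cells, skeletal muscle, Schwann cells and melanocytes, and erythroid cells. Some genes stand in several lists. Lists were tested with camera (limma 3.58.1, preset correlation 0.01), again with an estimated correlation, and with fry. A list's p-values were adjusted over the lists of a comparison. Human ATAC regions were tied to the nearest gene within 50 kb, and shares of changed genes were compared with Fisher's exact test (2-sided, adjusted over the tests made). Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for joins, Fisher tests and plots.

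Genes named are JUN and CD36, then the 6 largest rises and falls over the 4 skin types (3 in other human comparisons) among genes with adjusted p under the threshold, a mean of at least 10 CPM in a group and no overlap of replicates, and from each list up to 4 passing members by size of change, or the most expressed member where none passed. Regions named are those nearest JUN and CD36 and, in full or in part, the 3 largest gains and losses with a mean of at least 50 counts in a group. After values were seen, some genes whose absence can be inherited, and regions of comparisons between donors, were left unnamed for privacy, and the next gene took the place. A few other genes are not reported here.

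Alternatives tried were a filter at a mean of 10 counts, no filter, DESeq2's size factors (RLE), total counts only, the replicate letter as a block, only the groups compared, each replicate or skin type left out, no skin type term, 16 libraries as separate samples, DESeq2 1.42.0, and a region to gene distance of 5 kb or any. Added after the data were seen were an abundance-trended scaling (loess, span 0.3) and the test of the labelled KO effect in hypertrophic scar against each other skin type. Pseudocount and low-value alternatives for normalized values did not apply to counts. A test of the AP-1 motif was not run for want of a genome.

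For the comparisons listed next, edgeR's test was tried on simulated data with 200 features changed by 2- or 4-fold. The shares recovered at the smaller and the larger fold were 21% and 52% in mouse RNA (lipofibroblasts), 53% and 90% in human RNA (normal skin), 47% and 85% over the 4 types, 19% and 76% in mouse ATAC (lipofibroblasts), 14% and 66% in human ATAC (normal skin) and 22% and 78% over the 4 types. False calls were 6 of 79, 10 of 153, 8 of 140, 9 of 104, 3 of 83 and 3 of 103. Replicates of every group differed by more than sampling noise, with chi-square per degree of freedom from 1.91 to 39.4, so each library counted as 1 sample.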

Results

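The series addressed what the AP-1 transcription factor JUN, and with it the fatty acid receptor CD36, do in skin scarring. RNA-seq and ATAC-seq profiled fibroblasts of wounded JUN or control mice and cultured human fibroblasts of 4 skin types, unedited or labelled JUN KO. Induction of c-Jun was not tested. Counted reads per library numbered 30.1 to 35.9 M in mouse RNA, 7.25 to 11.3 M in human RNA and 6.63 to 25.1 M in human ATAC. Mouse ATAC libraries titled JUN held 13.6 to 20.2 M reads and the control libraries 3.87 to 8.47 M, so that depth and genotype run together there. The genotype entry of the 4 former names the control line, so they are called libraries titled JUN below.

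JUN transcript, read first because it was the edited gene, was not lower over the 4 skin types in the libraries labelled JUN KO. In normal skin it stood at 202 and 216 CPM in the unedited and 340.1 and 183 CPM in the labelled KO libraries, and in scar at 272 and 126 against 275 and 249 CPM. Hypertrophic scar cells had 325 and 192 CPM unedited and 133 and 100.4 CPM labelled KO, and keloid cells 207 and 89.1 against 179 and 124 CPM. CD36, which carries long-chain fatty acids into cells, fell over the 4 types by 2.90 ± 0.26 on the log2 scale (n = 4 per group, adjusted p = 0.00242 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its level in unedited hypertrophic scar cells was 276 and 245 CPM, against 2.54 and 2.82 in normal skin, 7.25 and 7.99 in scar and 2.84 and 1.82 in keloid. The labelled KO libraries had 28.1 and 33.1 CPM in hypertrophic scar, 0 and 0.479 in normal skin, 0.515 and 1.22 in scar and 0.768 and 0.702 in keloid.

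**Figure D1:**
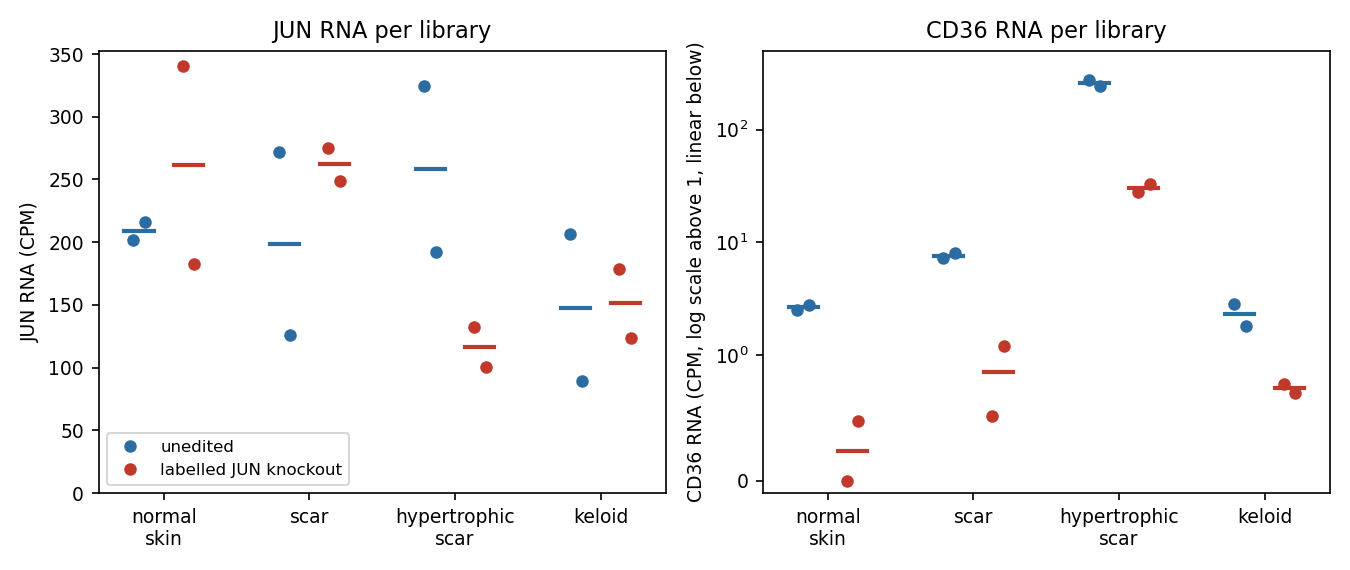
JUN RNA (left) and CD36 RNA (right) in CPM in each human RNA library, by skin type, for unedited and labelled JUN KO cells, with points for the 2 libraries of a group and a bar at their mean. CD36 stands at 276 and 245 CPM in unedited hypertrophic scar cells and under 10 CPM in the unedited cells of the other types, and is lower in the labelled KO libraries of all 4 types, while JUN is not.

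The fitted JUN change over the 4 types was -0.07 ± 0.25 (adjusted p = 0.857). By type it was 0.32 ± 0.39 in normal skin, 0.40 ± 0.39 in scar and 0.03 ± 0.40 in keloid, none past the threshold, and -1.15 ± 0.40 in hypertrophic scar (adjusted p = 0.040). That fall lost its call with total counts only (adjusted p = 0.0531), with DESeq2 (0.0741), and without unedited A (0.313), labelled KO A (0.0722) or labelled KO B (0.215), over a range of 2.26e-15 to 0.313 for the alternatives run. The JUN effect in hypertrophic scar was not shown to differ from that in normal skin (adjusted p = 0.133), scar (0.138) or keloid (0.260). CD36 changed by -3.49 ± 0.60 in normal skin (adjusted p = 0.000249), -3.14 ± 0.37 in scar (1.43e-05), -3.09 ± 0.21 in hypertrophic scar (3.76e-08) and -1.66 ± 0.48 in keloid (0.0195). The keloid call was lost with only the groups compared (adjusted p = 0.0590) and without unedited A (0.157), labelled KO A (0.0814) or labelled KO B (0.113), over a range of 0.00103 to 0.157. In a fit without the skin type term CD36 over the 4 types did not pass (adjusted p = 0.328, range over alternatives 2.61e-16 to 0.328).

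Over the 4 skin types, the labelled KO libraries had more RNA of the protease gene MMP12 and the protease inhibitor gene TFPI2 and less of ADH1B, PPL and CCN5. MMP12, macrophage elastase, rose from 0.238 ± 0.265 to 11.7 ± 15.7 CPM (5.25 ± 0.75, n = 4 per group), and TFPI2, a Kunitz-type protease inhibitor, from 7.90 ± 3.67 to 197 ± 100.3 CPM (4.64 ± 0.17). The other largest rises were KRTAP2-3 (5.08 ± 0.26), SAMD11 (4.89 ± 0.38), NEFM (4.46 ± 0.44) and EXTL1 (4.22 ± 0.52), of which KRTAP2-3 is a keratin-associated protein and NEFM a neurofilament subunit. ADH1B, an alcohol dehydrogenase, fell from 199 ± 243 to 0.736 ± 1.31 CPM (-8.21 ± 0.88), PPL, the desmosomal protein periplakin, from 189 ± 188 to 1.07 ± 0.790 CPM (-7.24 ± 0.40), and CCN5, a matricellular protein, from 709 ± 669 to 25.0 ± 21.3 CPM (-4.96 ± 0.28). IGSF10 (-6.62 ± 0.33), PKD1L2 (-4.59 ± 0.86) and CHI3L1 (-4.58 ± 1.17) completed the largest falls, CHI3L1 being a chitinase-like secreted protein. All of these moved the same way in 4 of 4 types. In all, 2597 (1413 higher and 1184 lower) of 11727 genes were called, 2591 (1164 higher and 1427 lower) with total counts only and 1269 without the skin type term. Leaving out 1 skin type at a time, the count fell to 1074 without hypertrophic scar, 1241 without scar, 1670 without normal skin and 1715 without keloid.

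**Figure D2:**
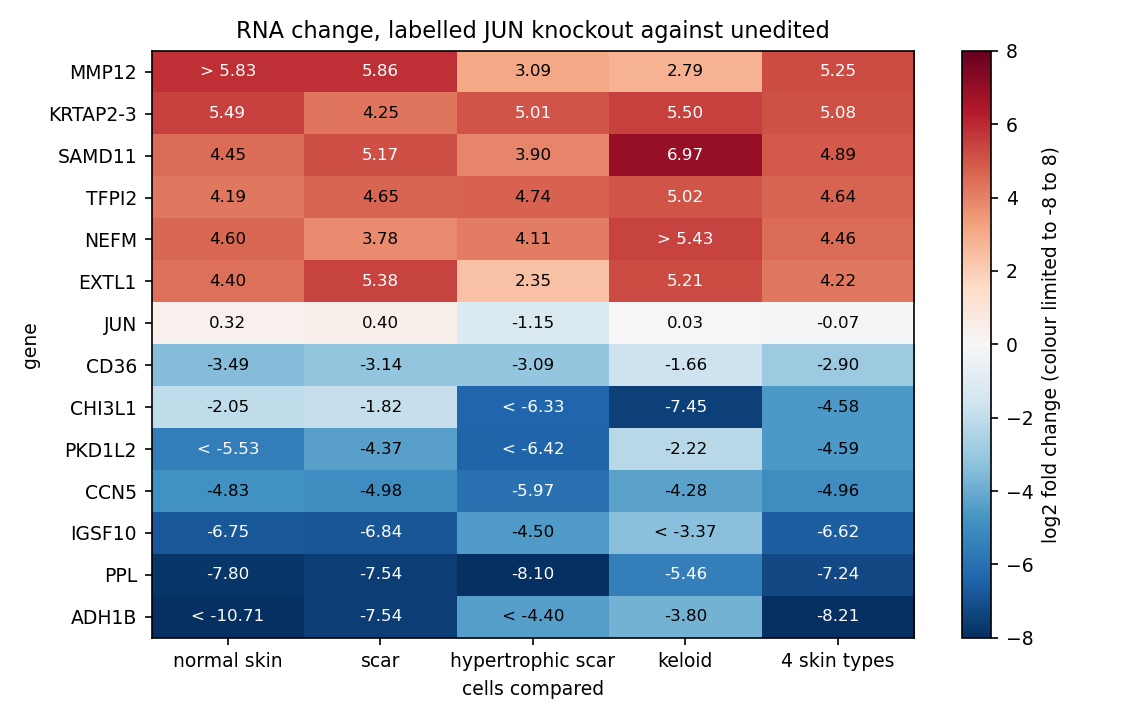
Heat map of the labelled JUN KO against unedited log2 fold change (colour, and value in each cell) for JUN, CD36 and the 12 genes with the largest changes over the 4 skin types, in columns for each skin type and for the 4 together, where < and > mark bounds against 0 counts. The 6 rising and 6 falling genes keep their sign in every column, and JUN does not.

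Of the lists fixed beforehand, interferon-induced genes and keratinocyte markers moved furthest upwards. Medians beside list counts are log2 fold changes. Of the interferon list 10 of 19 rose (median 1.25), among them OASL (5.01 ± 0.53) and RSAD2 (4.14 ± 0.81), but in keloid alone its median was 0.10. Of keratinocyte markers, in cultures labelled fibroblasts, 7 of 9 rose (median 1.71), including the basal keratins KRT15 (5.14 ± 0.56) and KRT14 (3.57 ± 0.51) and the desmosomal DSP (1.71 ± 0.21). In TGF-beta and BMP signalling 9 of 17 rose and 2 fell (median 0.67). Rising members included the inhibitors of DNA binding ID3 (2.82 ± 0.28) and ID1 (2.47 ± 0.56), the activin subunit gene INHBA (2.53 ± 0.16) and the BMP antagonist NOG (3.29 ± 0.88). Of the HOX genes, which mark position along the body, 6 of 28 rose (median 0.59), for example HOXB5 (1.34 ± 0.28). Of papillary fibroblast genes of the upper dermis 4 of 8 fell (median -1.21), such as NTN1 (-3.56 ± 0.83) and DPP4 (-2.32 ± 0.27). In lipid uptake and storage 4 of 14 fell (median -0.92), the complement factor adipsin CFD (-4.24 ± 0.18), the desaturase SCD (-2.25 ± 0.38) and the fatty acid transporter SLC27A1 (-0.89 ± 0.16) besides CD36. When adjusted over the list alone, 2 rose and 6 fell for lipid uptake and storage, with the others unchanged. Camera passed these 6 lists and no others, at adjusted p = 0.000309 to 0.0274. None held at adjusted p = 0.469 to 0.515 with an estimated correlation. 

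**Figure D3:**
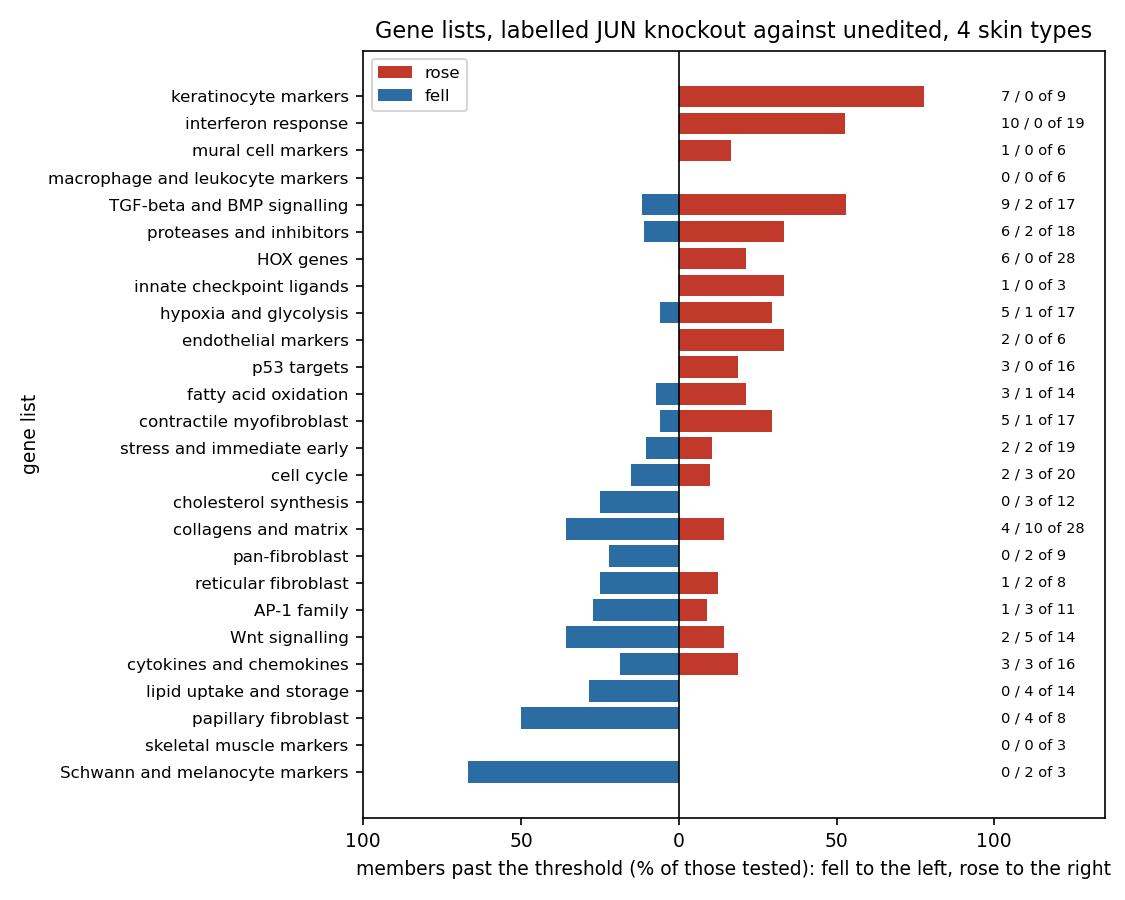
Share of measured members of each gene list that rose (bars to the right) or fell (bars to the left) in labelled JUN KO against unedited cells over the 4 skin types, in percent, with the counts written beside the bars. Keratinocyte markers (7 of 9 rose) reach furthest right.

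The other lists over the 4 types did not pass camera, and their members went both ways or few passed. In the AP-1 family 1 of 11 rose and 3 fell (median -0.66), with MAF (-2.29 ± 0.44) and JUND (-0.66 ± 0.17) down and FOSL1 (0.94 ± 0.20) up. Among collagens and matrix 4 of 28 rose and 10 fell (median -0.41), with COL14A1 (-3.77 ± 0.32) and TNC (-2.18 ± 0.30) down and the hyaluronan synthase HAS2 (2.34 ± 0.32) up. In the contractile list 5 of 17 rose and 1 fell (median 0.00), the rises led by ANKRD1 (4.42 ± 0.47) and CCN2 (3.17 ± 0.21). Among proteases and inhibitors 6 of 18 rose and 2 fell (median 0.65), with TIMP3 (2.06 ± 0.30) up and ADAMTS5 (-1.77 ± 0.33) down. In Wnt signalling 2 of 14 rose and 5 fell (median -0.72), where SFRP4 (-3.24 ± 0.61) and AXIN2 (-2.50 ± 0.22) fell and the inhibitor DKK1 (2.22 ± 0.53) rose. In the cell cycle list 2 of 20 rose and 3 fell, such as cyclin D1 CCND1 (2.40 ± 0.31) and the replication factor MCM2 (-0.85 ± 0.15). In cholesterol synthesis 3 of 12 fell, among them INSIG1 (-1.07 ± 0.27) and SREBF2 (-0.96 ± 0.15). Among cytokines and chemokines 3 of 16 rose and 3 fell, with CXCL10 (4.31 ± 1.22) up and CXCL2 (-2.94 ± 0.45) down. In fatty acid oxidation 3 of 14 rose and 1 fell, with the coactivator PPARGC1A (-3.96 ± 0.38) down and SLC25A20 (0.98 ± 0.15) up. With members adjusted over the list alone, 1 rose and 4 fell for the AP-1 family, 7 and 12 for collagens and matrix, 7 and 2 for proteases and inhibitors, 2 and 6 for Wnt signalling, 3 and 5 for cytokines and chemokines and 4 fell for cholesterol synthesis, with the others unchanged. The median, mean and test direction differed in sign for contractile genes (median 0.00, mean 0.40, camera upwards).

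In hypoxia and glycolysis 5 of 17 rose and 1 fell, with ADM (-1.66 ± 0.21) down and SLC2A1 (1.47 ± 0.35) up. Among stress and immediate early genes 2 of 19 rose and 2 fell, with SOCS3 (-2.32 ± 0.22) down and the heat shock gene HSPB1 (0.97 ± 0.15) up. Of the p53 targets 3 of 16 rose, such as CDKN1A (0.99 ± 0.19). Of pan-fibroblast genes 2 of 9 fell, PDGFRB (-1.59 ± 0.26) and TWIST1 (-0.55 ± 0.13), and of reticular fibroblast genes 1 of 8 rose and 2 fell, with CTSK (-2.13 ± 0.30) down and CDH2 (1.89 ± 0.20) up. Of endothelial markers 2 of 6 rose, FLT1 (2.43 ± 0.64) and KDR (at least 11.5-fold higher), of mural cell markers 1 of 6 rose, MCAM (1.80 ± 0.32), and of Schwann and melanocyte markers 2 of 3 fell, MITF (-2.61 ± 0.30) and MBP (-2.06 ± 0.33). Of the innate checkpoint ligands 1 of 3 rose, CALR (0.54 ± 0.12). Of 6 macrophage and leukocyte markers and of 3 skeletal muscle markers 0 passed edgeR's test. At an unadjusted p under 0.05 the former had 1 higher and the latter 1 higher and 1 lower. The most expressed members were LYZ at 3.39 ± 0.674 against 4.05 ± 0.652 CPM and DES at 1.13 ± 1.11 against 6.94 ± 8.68 CPM. Counts adjusted over the list alone became 5 rose and 3 fell for hypoxia and glycolysis, 2 and 4 for stress and immediate early, 1 and 4 for reticular fibroblast genes, 3 and 1 for mural cell markers, 1 and 1 for skeletal muscle markers and 2 rose for innate checkpoint ligands, with the others unchanged. 

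The direction of change was shared between skin types more often than for independent lists. Of 11125 genes, 571 were called higher and 407 lower in the labelled KO libraries of all 4 types, where independent lists would share 5.85 and 4.11. Of 6288 genes called in any type 343 were called opposite ways. Across genes, which are not independent replicates, fold changes of pairs of types correlated at Pearson's r from 0.453 to 0.584.

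In normal skin cells labelled JUN KO, most papillary and reticular fibroblast genes fell and most interferon and keratinocyte genes rose. ADH1B was at least 1673-fold lower (284 ± 11.9 CPM unedited, 0 counts labelled KO, n = 2 per group). SCARA5 (at least 94.6-fold lower) and TMEM176A (at least 64.6-fold lower) were the next largest falls. The largest rises were those of the light neurofilament gene NEFL (at least 85.7-fold higher), RSAD2 (at least 81.4-fold higher) and KCTD4 (16.6 against 0.101 CPM). Of papillary fibroblast genes 6 of 8 fell (median -1.75), first NTN1 (0.114 against 23.5 CPM). Of reticular fibroblast genes 2 of 8 rose and 6 fell, with CLEC3B (-6.08 ± 0.21) down. Of pan-fibroblast genes 1 of 9 rose and 5 fell, such as PDGFRB (-2.33 ± 0.24). Among collagens and matrix 9 of 28 rose and 15 fell: COL14A1 (-4.71 ± 0.29), decorin DCN (-3.25 ± 0.10) and tenascin TNC (-2.87 ± 0.26) were down and HAS2 (3.20 ± 0.12) up. In the AP-1 family 1 of 11 rose and 5 fell, the falls led by FOSB (-4.27 ± 0.62) and MAF (-4.03 ± 0.49), and of Schwann and melanocyte markers 3 of 3 fell, such as MITF (-3.22 ± 0.46) and MBP (-2.82 ± 0.16). Among interferon genes 11 of 19 rose and 2 fell (median 1.18), including OAS1 (at least 5.29-fold higher) and IFI44L (3.43 ± 0.35). Keratinocyte markers went the same way: 6 of 10 rose (median 2.07, or 1.68 with members at 0 counts set to their bound), with IVL (at least 2.95-fold higher), KRT17 (3.52 ± 0.35) and KRT14 (2.54 ± 0.28). In TGF-beta and BMP signalling 10 of 17 rose and 4 fell, the largest being NOG (4.04 ± 0.41). Contractile genes (of which 8 of 17 rose and 4 fell) included ANKRD1 (6.55 ± 0.37). The cell cycle list, in which 9 of 20 rose and 3 fell, included CCND1 (3.06 ± 0.11). In lipid uptake and storage 3 of 13 rose and 6 fell, with LEP (at least 3.90-fold higher), CFD (-4.31 ± 0.16) and FABP3 (-4.25 ± 0.25) beside CD36. When adjusted over the list alone, 10 rose and 3 fell for the cell cycle list, 11 and 4 for TGF-beta and BMP signalling and 7 rose for keratinocyte markers, with the others unchanged. By camera these lists and no others passed, at adjusted p = 0.00104 to 0.0474. The calls were lost at adjusted p = 0.0882 to 0.272 with an estimated correlation. In normal skin 4367 genes were called (2249 higher and 2118 lower), and 4385 (1822 higher and 2563 lower) with total counts only. 

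In scar cells labelled JUN KO, most genes of the proteases and inhibitors list and the interferon list rose. MMP3 (stromelysin) went from 162 ± 23.3 to 2499 ± 6.95 CPM (3.95 ± 0.18, n = 2 per group) and MMP12 from 0.583 ± 0.0231 to 34.8 ± 0.353 CPM. Of proteases and inhibitors 10 of 18 rose and 2 fell (median 0.80), MMP10 (3.28 ± 0.86) and MMP1 (2.99 ± 0.24) among them. The other largest rises were NOG (14.6 against 0.0499 CPM) and the transglutaminase gene TGM2 (6.27 ± 0.38), and the largest falls PPL (-7.54 ± 0.37), ADH1B (-7.54 ± 0.26) and SCARA5 (0.0553 against 18.6 CPM). Of the interferon list 13 of 19 rose (median 1.90), first OASL (2.52 against 0.0567 CPM) and IFI44L (4.94 ± 0.28). In TGF-beta and BMP signalling 10 of 17 rose (median 1.02), with INHBA (2.73 ± 0.13). Of keratinocyte markers 5 of 10 rose, such as KRT17 (5.97 against 0.0567 CPM), and of HOX genes 7 of 28 rose, such as HOXB5 (1.99 ± 0.29). Downwards, of cytokines and chemokines 5 of 16 fell (median -0.94, or -0.64 with members at 0 counts set to their bound), among them the monocyte attractant CCL2 (-2.62 ± 0.18) and CXCL2 (-3.49 ± 0.52). In Wnt signalling 2 of 14 rose and 7 fell, led by SFRP4 (-3.26 ± 0.27). Collagens and matrix, in which 8 of 28 rose and 12 fell, included COL14A1 (-3.49 ± 0.26). Of papillary fibroblast genes 2 of 8 rose and 4 fell, with NTN1 (-3.05 ± 0.41) and DPP4 (-1.83 ± 0.18) down and PRDM1 (1.58 ± 0.40) up. Of Schwann and melanocyte markers 2 of 3 fell, MBP (-2.84 ± 0.15) and MITF (-2.44 ± 0.43). With members adjusted over the list alone, 8 rose and 13 fell for collagens and matrix, 2 and 5 for papillary fibroblast genes, 11 and 3 for proteases and inhibitors, 10 and 2 for TGF-beta and BMP signalling and 6 rose for keratinocyte markers, with the others unchanged. Besides these lists none passed camera, which gave them adjusted p = 9.63e-11 to 0.0347. The call held for the interferon list, proteases and inhibitors and TGF-beta and BMP signalling at adjusted p = 0.00635 to 0.0118 with an estimated correlation, and the others were lost at adjusted p = 0.0644 to 0.340 with an estimated correlation. In scar 2667 genes were called (1415 higher and 1252 lower), and 2691 (1166 higher and 1525 lower) with total counts only. Leaving out 1 library at a time, the count fell to 1672 without scar unedited A, 1672 without scar KO B and 1682 without scar KO A.

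In hypertrophic scar cells labelled JUN KO, every measured gene of cholesterol synthesis fell and most interferon genes rose. Of cholesterol synthesis genes 12 of 12 fell (median -1.37), including LSS (-2.20 ± 0.55) and FDPS (-1.92 ± 0.50). Of lipid uptake and storage genes 1 of 13 rose and 7 fell (median -1.40, or -1.35 with members at 0 counts set to their bound). SCD fell from 1533 ± 276 to 116 ± 21.2 CPM (-3.72 ± 0.20, n = 2 per group) and the fatty acid binding protein gene FABP3 from 83.0 ± 12.3 to 2.23 ± 0.352 CPM (-5.20 ± 0.25), beside CD36, CFD (-4.48 ± 0.26) and LEP (at least 2.55-fold lower). Of the interferon list 16 of 19 rose (median 1.40), with RSAD2 (4.69 ± 0.33) and ISG15 (3.05 ± 0.17). Keratinocyte markers, of which 6 of 10 rose (median 0.99), included KRT15 (at least 10.6-fold higher) and KRT14 (4.85 ± 0.37). FOXS1, a forkhead transcription factor, led the rises at 1.12 ± 0.0901 to 113 ± 6.42 CPM (6.63 ± 0.32), followed by OASL (10.9 against 0.177 CPM) and KRTAP2-3 (5.01 ± 0.37). PKD1L2 (at least 85.6-fold lower), CHI3L1 (at least 80.2-fold lower) and PPL (0.0549 against 17.3 CPM) led the falls. Adjusted over the list alone, the counts were the same. Camera passed these lists and no others, at adjusted p = 1.21e-12 to 0.00695. It held for cholesterol synthesis and the interferon list at adjusted p = 0.00290 with an estimated correlation, and the others were lost at adjusted p = 0.0739 to 0.132 with an estimated correlation. In hypertrophic scar 3348 genes were called (1702 higher and 1646 lower). 

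In keloid cells labelled JUN KO, most genes of the cell cycle list and of cytokines and chemokines fell. Of the cell cycle list 1 of 20 rose and 15 fell (median -0.86), among them the proliferation marker MKI67 (-2.14 ± 0.35) and TOP2A (-1.80 ± 0.19). Of cytokines and chemokines 1 of 16 rose and 11 fell (median -2.40, or -2.02 with members at 0 counts set to their bound). CCL2 fell from 317 ± 32.7 to 21.2 ± 1.77 CPM (-3.90 ± 0.18, n = 2 per group), and CCL11 (at least 11.2-fold lower), CSF2 (at least 8.92-fold lower) and CCL8 (at least 2.21-fold lower) dropped to 0 counts. Of HOX genes 14 of 28 rose (median 1.35, or 1.30 with members at 0 counts set to their bound), for example HOXD1 (2.48 ± 0.80). The largest rise was SCUBE3, a secreted glycoprotein gene, from 2.22 ± 0.649 to 671 ± 57.6 CPM (8.24 ± 0.33), followed by KRT15 (10.3 against 0.103 CPM) and DNER (6.42 ± 0.38). The largest falls were CHI3L1 (-7.45 ± 0.25), PTGDS (-6.37 ± 0.57) and PPL (-5.46 ± 0.44), PTGDS making prostaglandin D2. In lipid uptake and storage 7 of 13 fell, with CFD (-3.57 ± 0.24) and LEP (-2.32 ± 0.35). Of papillary fibroblast genes 4 of 8 fell, first NTN1 (-2.55 ± 0.69), and of reticular fibroblast genes 2 of 8 rose and 4 fell, with CDH2 (2.15 ± 0.11) up and GPX3 (-1.86 ± 0.13) down. Schwann and melanocyte markers went down too: 2 of 3 fell, MITF (-1.86 ± 0.46) and MBP (-1.21 ± 0.15). Mural cell markers went up: 4 of 6 rose, led by HEYL (2.91 ± 0.79). Among keratinocyte markers 6 of 10 rose, such as KRT14 (4.89 ± 0.44) besides KRT15. In TGF-beta and BMP signalling 8 of 17 rose and 3 fell, with ID1 (2.67 against 0.0536 CPM) and ID3 (3.37 ± 0.14) up and BMP6 (-2.71 ± 0.54) down. Counts adjusted over the list alone became 2 rose and 16 fell for the cell cycle list, 2 and 12 for cytokines and chemokines, 9 and 4 for TGF-beta and BMP signalling, 15 rose for HOX genes and 5 fell for papillary fibroblast genes, with the others unchanged. By camera these lists and no others passed, at adjusted p = 3.29e-06 to 0.0467. Those that held were the cell cycle list, cytokines and chemokines, HOX genes and lipid uptake and storage at adjusted p = 0.00952 to 0.0448 with an estimated correlation, and the others were lost at adjusted p = 0.0540 to 0.280 with an estimated correlation. In keloid 2783 genes were called (1488 higher and 1295 lower), and 2711 (1202 higher and 1509 lower) with total counts only. With 1 library left out, the count fell to 1703 without keloid KO B.

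The unedited cells of each scar type were compared with unedited normal skin cells, each from 1 patient. In scar cells more Wnt and cell cycle genes were higher than lower, and more contractile genes lower than higher. SFRP4, a secreted Wnt antagonist gene, stood at 57.0 ± 1.32 against 2.66 ± 0.358 CPM (4.40 ± 0.30, n = 2 per group). In Wnt signalling 5 of 14 were higher and 3 lower (median 0.53), with SFRP2 (2.54 ± 0.18). Of the cell cycle list 10 of 20 were higher (median 1.03), first PLK1 (1.63 ± 0.22). Of the interferon list 8 of 19 were higher and 1 lower (median 0.37, or 0.34 with members at 0 counts set to their bound), among them RSAD2 (at least 6.29-fold higher) and ISG20 (-2.11 ± 0.26). Contractile genes, of which 1 of 17 were higher and 6 lower (median -0.51, or -0.39 with members at 0 counts set to their bound), included DES (-3.50 ± 0.62) and CNN1 (-1.65 ± 0.19). Of mural cell markers 3 of 6 were lower, such as NOTCH3 (-1.88 ± 0.19), and of endothelial markers 2 of 4 were lower, FLT1 (-2.82 ± 0.72) and CDH5 (0.163 against 2.97 CPM). Of HOX genes 4 of 28 were lower, such as HOXB5 (-1.15 ± 0.30). In the AP-1 family 4 of 11 were lower, first FOSB (-2.82 ± 0.52). Among stress genes 2 of 19 were higher and 5 lower, with GADD45B (0.91 ± 0.10) higher and HSPA1A (-0.91 ± 0.11) lower. Other large differences were RAB27B (3.81 ± 0.40) and ARFGEF3 (3.76 ± 0.58) upwards and aggrecan ACAN (-5.92 ± 0.60), OLFM2 (-4.36 ± 0.26) and KRT14 (-4.07 ± 0.42) downwards. CD36 was higher (1.5 ± 0.30, adjusted p = 0.00425), but not without normal unedited A (adjusted p = 0.0526, range over alternatives 2.23e-06 to 0.0526). JUN stood at -0.07 ± 0.39. When adjusted over the list alone, 1 were higher and 7 lower for contractile genes, 1 and 6 for HOX genes, 10 and 1 for the interferon list, 3 and 9 for stress and immediate early, 7 and 3 for Wnt signalling, 13 were higher for the cell cycle list and 4 were lower for mural cell markers, with the others unchanged. Besides these lists none passed camera, which gave them adjusted p = 1.95e-09 to 0.0251. The call held for the cell cycle list, contractile genes, the interferon list, stress and immediate early and Wnt signalling at adjusted p = 0.00405 to 0.0498 with an estimated correlation, and the others were lost at adjusted p = 0.0810 to 0.107 with an estimated correlation. Between scar and normal skin 1222 genes were called (694 higher and 528 lower), and 1289 (545 higher and 744 lower) with total counts only. In fits without 1 library, the count fell to 504 without normal unedited B, 530 without normal unedited A, 666 without scar unedited A and 730 without scar unedited B.

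Hypertrophic scar cells had far more CD36 RNA than normal skin cells, most contractile and interferon genes were higher and most papillary fibroblast genes lower. CD36 stood at 261 ± 22.1 against 2.68 ± 0.198 CPM (6.59 ± 0.27, n = 2 per group, adjusted p = 1.07e-10), and JUN at 259 ± 93.6 against 209 ± 10.3 CPM (0.31 ± 0.39, adjusted p = 0.633). DPT, which codes for dermatopontin, stood at 2.04 ± 0.460 against 2706 ± 34.9 CPM (-10.35 ± 0.20). The other largest differences were ADGRD1 (at least 535-fold lower) and TMEM176A (at least 58.6-fold lower) downwards and LETR1 (at least 124-fold higher), AJAP1 (at least 62.9-fold higher) and CD4 (13.8 against 0.0634 CPM) upwards. Of contractile genes 10 of 17 were higher and 2 lower (median 0.66), first ACTG2 (12.1 against 0.0634 CPM) and CNN1 (3.59 ± 0.16). Of the interferon list 13 of 19 were higher (median 1.14), first RSAD2 (at least 4.89-fold higher). In hypoxia and glycolysis 10 of 16 were higher and 1 lower (median 0.72), with ANKRD37 (1.95 ± 0.27), and in cholesterol synthesis 5 of 12 were higher (median 0.67), with SQLE (1.07 ± 0.12). Of papillary fibroblast genes 7 of 8 were lower (median -1.86), namely NTN1 (-4.73 ± 0.48) and APCDD1 (-2.52 ± 0.18) first. Among reticular fibroblast genes 1 of 8 were higher and 5 lower, with MFAP5 (-2.24 ± 0.11) lower and GPX3 (1.31 ± 0.14) higher. Among pan-fibroblast genes 4 of 9 were lower, TWIST2 (-3.16 ± 0.12) first. Among stress genes 2 of 19 were higher and 8 lower, such as KLF4 (-2.16 ± 0.24). With members adjusted over the list alone, 12 were higher and 2 lower for contractile genes and 7 were higher for cholesterol synthesis, with the others unchanged. Camera passed these lists and no others, at adjusted p = 2.04e-06 to 0.00804. All of them held at adjusted p = 0.010 to 0.0417 with an estimated correlation. Between hypertrophic scar and normal skin 2697 genes were called (1356 higher and 1341 lower). Total counts only moved the median log2 fold change from 0.01 to -0.15 and called 2955 (975 higher and 1980 lower). Leaving out 1 library at a time, the count fell to 1569 without normal unedited B and 1675 without normal unedited A.

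In keloid cells most cell cycle genes were higher and most HOX genes lower than in normal skin cells (n = 2 per group). Of the cell cycle list 15 of 20 were higher (median 1.53), first MKI67 (2.69 ± 0.37). Of cytokines and chemokines 7 of 16 were higher and 1 lower (median 1.72, or 1.37 with members at 0 counts set to their bound), with CSF2 (1.64 against 0.0634 CPM) and IL6 (3.22 ± 0.23) higher and CXCL12 (-3.22 ± 0.18) lower. In hypoxia and glycolysis 8 of 16 were higher and 2 lower (median 0.73), with the glucose transporter gene SLC2A1 at 154 ± 9.72 against 26.7 ± 1.03 CPM, beside HK2 (1.61 ± 0.23). Of HOX genes 1 of 28 were higher and 17 lower (median -1.45), led by HOXC5 (at least 6.08-fold lower). The hormone gene LEP was at least 171-fold higher at 28.7 ± 5.90 CPM against 0 counts, followed by PADI2 (at least 96.8-fold higher) and ELOVL2 (at least 75.9-fold higher). EPB41L3 (at least 365-fold lower) and RASL12 (at least 82.5-fold lower) were among the largest differences downwards. Contractile genes, of which 9 of 17 were higher and 3 lower, included DES (-4.89 ± 0.73) and ANKRD1 (4.42 ± 0.42). Among interferon genes 9 of 19 were higher and 2 lower, such as OAS1 (at least 8.85-fold higher). In cholesterol synthesis 5 of 12 were lower, such as FDFT1 (-0.84 ± 0.11). Among pan-fibroblast genes 1 of 9 were higher and 4 lower, with TWIST2 (-2.18 ± 0.11) lower and CD9 (1.81 ± 0.14) higher. Stress genes, of which 1 of 19 were higher and 8 lower, included FOSB (-4.09 ± 0.59). CD36 (-0.19 ± 0.36, adjusted p = 0.746) and JUN (-0.50 ± 0.39, 0.400) did not pass. JUN passed without a filter or with the replicate block. Counts adjusted over the list alone became 11 higher and 4 lower for contractile genes, 9 and 1 for cytokines and chemokines, 2 and 20 for HOX genes, 9 and 4 for hypoxia and glycolysis, 1 and 5 for pan-fibroblast genes and 7 lower for cholesterol synthesis, with the others unchanged. By camera these lists and no others passed, at adjusted p = 1.03e-10 to 0.0269. The cell cycle list, cholesterol synthesis, contractile genes, cytokines and chemokines, HOX genes and stress and immediate early held with an estimated correlation. Their adjusted p was 0.00260 to 0.0467, and the others were lost at 0.0537 to 0.0779. Between keloid and normal skin 2845 genes were called (1462 higher and 1383 lower), and 2882 (1219, 1663) with total counts only. With 1 library left out, the count fell to 1711 without normal unedited B and 1799 without normal unedited A.

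Over the 4 skin types, more regions near fibroblast genes were lost than gained in the libraries labelled JUN KO (n = 4 per group). Of regions nearest collagen and matrix genes 27 of 410 were gained and 78 lost (median -0.22). Among papillary fibroblast regions 6 of 131 were gained and 32 lost (median -0.26), and among reticular fibroblast regions 8 of 144 were gained and 28 lost (median -0.23). The largest losses were chromosome 3, 67538540 to 67538993 (-5.10 ± 0.61, 166272 bp from SUCLG2), chromosome 7, 7518871 to 7519521 (-4.38 ± 0.52, 56264 bp from COL28A1) and chromosome 10, 6830108 to 6830607 (-4.26 ± 0.49, 8798 bp from LINC00707). The largest gains were chromosome 8, 115874060 to 115874568 (3.48 ± 0.63, 805925 bp from TRPS1), chromosome 11, 5247625 to 5247902 (3.45 ± 0.38, 538 bp from HBB) and chromosome 11, 5246049 to 5247414 (3.44 ± 0.17, 1570 bp from HBB), TRPS1 being a GATA-type repressor and HBB beta-globin. When adjusted over the list alone, 28 were gained and 94 lost for collagens and matrix, 9 and 34 for papillary fibroblast genes and 10 and 29 for reticular fibroblast genes. Besides these lists none passed camera, which gave them adjusted p = 0.0186 to 0.0215. None of them held at adjusted p = 0.446 to 0.474 with an estimated correlation. Among erythroid marker regions, which include those of HBB, 4 of 15 were gained and 1 lost (median 0.05), and among macrophage and leukocyte regions 11 of 92 were gained and 2 lost (median 0.30). Adjusted over the list alone, the counts were the same. Of 259434 regions 53335 were called (24450 gained and 28885 lost). Total counts only moved the median log2 fold change from 0.02 to 0.16 and called 53623 (33285 higher and 20338 lower). Leaving out 1 skin type at a time, the count fell to 26540 without scar and 32273 without hypertrophic scar. Without the skin type term 15 regions passed.

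JUN had 13 tested regions, 1 gained and 4 lost over the 4 types. The one closest to the gene start (chromosome 1, 59248616 to 59250470, 242 bp away) had 71.0 ± 16.5 against 77.5 ± 13.8 CPM (-0.14 ± 0.10, adjusted p = 0.327), and the largest change was at chromosome 1, 59235398 to 59236026 (-1.78 ± 0.33). The former was lost in keloid cells labelled KO (-0.34 ± 0.14, adjusted p = 0.0478) and less open in unedited scar than normal skin cells (-0.49 ± 0.14, 0.0123). CD36 had 12 tested regions, 2 gained and 2 lost. The closest to its start (7605 bp away, chromosome 7, 80223489 to 80224308) stood at 0.00 ± 0.35. The largest change was 1.91 ± 0.54 (chromosome 7, 80214125 to 80214459). By type, CD36 regions ran with its RNA in normal skin and scar cells labelled KO, where 2 in each were lost and none gained (first chromosome 7, 80263705 to 80264263, -2.02 ± 0.28, and chromosome 7, 80264862 to 80265371, -1.10 ± 0.29), and in unedited scar against normal skin cells, where 1 was more open and none less open (1.43 ± 0.34). In keloid cells labelled KO 2 were gained and 2 lost. Against the fall of CD36 RNA, chromosome 7, 80240408 to 80241481 was gained in hypertrophic scar and keloid cells labelled KO (2.88 ± 0.64 and 2.24 ± 0.34). In unedited hypertrophic against normal skin cells, where CD36 RNA was higher, 4 of its 12 regions were less open and the rest had no call.

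By skin type, more papillary fibroblast regions were lost than gained in normal skin and scar cells labelled JUN KO (n = 2 per group). In normal skin 1 of 127 were gained and 29 lost (median -0.39) and in scar 5 of 127 were gained and 37 lost (median -0.36). Camera gave adjusted p = 0.00201 and 0.000678, and these held at adjusted p = 0.0235 and 0.0184 with an estimated correlation. In hypertrophic scar, of collagen and matrix regions 20 of 403 were gained and 64 lost (median -0.23). Their camera adjusted p = 0.00370 became adjusted p = 0.105 with an estimated correlation. In keloid, regions of 7 lists passed downwards, led by stress and immediate early genes, of whose regions 16 of 228 were gained and 69 lost (median -0.33). Next came the AP-1 family, where 11 of 121 were gained and 41 lost (median -0.43), and reticular fibroblast genes, where 15 of 143 were gained and 36 lost (median -0.33). Gained and lost were 35 and 95 of 403 for collagens and matrix and 22 and 61 of 214 for cytokines and chemokines. They were 16 and 55 of 206 for pan-fibroblast genes and 15 and 41 of 209 for proteases and inhibitors. With members adjusted over the list alone in keloid, 13 were gained and 46 lost for the AP-1 family, 29 and 65 for cytokines and chemokines, 17 and 58 for pan-fibroblast genes, 14 and 41 for proteases and inhibitors, 15 and 37 for reticular fibroblast genes and 16 and 73 for stress and immediate early, with the other list unchanged. Camera passed these 7 lists and no others, at adjusted p = 0.000487 to 0.0414. With an estimated correlation pan-fibroblast and reticular fibroblast genes held (adjusted p = 0.0194), the others not (0.0839 to 0.20). Within 1 kb of a gene start 43.4% of keloid regions were lost (median -0.43), against 13.1% farther. Top 10 regions held 0.22 to 0.24% of labelled KO reads and 0.35 to 0.37% of unedited. How these bear on the lists was not tested. Adjusted over the list alone, papillary counts were 1 gained and 31 lost in normal skin and 7 and 40 in scar. Collagens and matrix had 23 and 70 in hypertrophic scar. Called were 48791 regions in normal skin (22141 gained, 26650 lost), 45922 in scar (21597, 24325), 30925 in hypertrophic scar (14015, 16910) and 74474 in keloid (37145, 37329). Total counts only gave 30460 (16143, 14317) in hypertrophic scar, 45304 (29365, 15939) in scar and 71896 (44848, 27048) in keloid. The median log2 fold change moved from 0.04 to 0.19 in scar and 0.00 to 0.14 in keloid.

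Across types, changes of chromatin were shared as well: 2538 regions were gained and 4311 lost in all 4, where independent lists would share 16.8 and 27.6. Pairs of types correlated across regions at r from 0.372 to 0.502. Regions within 1 kb of a gene start were gained in 1.93% and lost in 14.0% of cases over the 4 types, and farther regions in 9.97% and 10.9%. The types differed in this: the shares gained and lost within 1 kb were 8.05% and 7.13% in normal skin, 2.12% and 16.7% in scar, 2.14% and 4.13% in hypertrophic scar and 2.57% and 43.4% in keloid. With 1 library left out, the normal skin count moved to 28139 without normal unedited A and 30612 without normal KO B, and the scar count to 19667 without scar unedited A, 19877 without scar KO B and 27043 without scar unedited B. The hypertrophic scar count moved to 15957 without hypertrophic scar unedited B, 20215 without hypertrophic scar KO A and 20271 without hypertrophic scar unedited A, and the keloid count to 42384 without keloid unedited B, 43312 without keloid KO B, 43765 without keloid KO A and 44327 without keloid unedited A.

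Between unedited skin types, more contractile gene regions were more open than less open in hypertrophic scar and keloid cells against normal skin cells (n = 2 per group). In hypertrophic scar 50 of 222 were more open and 11 less open (median 0.38), and in keloid 57 of 222 were more open and 15 less open (median 0.37). Of papillary fibroblast regions in hypertrophic scar 8 of 127 were more open and 40 less open (median -0.56). Of HOX regions in keloid 8 of 107 were more open and 47 less open (median -0.82), and of skeletal muscle regions in scar 6 of 62 were more open and 10 less open (median -0.59). Camera gave adjusted p = 0.00127 and 0.00767 for the contractile regions, lost at adjusted p = 0.235 and 0.186 with an estimated correlation. The papillary and HOX calls (adjusted p = 9.78e-06 and 1.43e-08) held at adjusted p = 0.00915 and 0.0433 with an estimated correlation. The skeletal muscle call (adjusted p = 0.0239) was lost at adjusted p = 0.181 with an estimated correlation. Adjusted over the list alone, the contractile counts were 59 more open and 11 less open in hypertrophic scar and 64 more open and 16 less open in keloid. The papillary count became 10 more open and 45 less open, the HOX count 9 more open and 49 less open and the skeletal muscle count 7 more open and 15 less open. Called were 28018 regions in scar (18083 higher, 9935 lower), 46211 in hypertrophic scar (22012, 24199) and 58362 in keloid (32262, 26100). With only the groups compared, scar gave 25396 (13346 higher and 12050 lower). With 1 library left out the count in scar moved to 14090 without scar unedited A, 14169 without scar unedited B, 14339 without normal unedited A and 18359 without normal unedited B. In keloid it moved to 36056 without normal unedited A, 38182 without keloid unedited A and 38380 without keloid unedited B. 

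Genes near regions that closed fell more often than other genes. Over the 4 types, 15.7% of genes with any lost region within 50 kb fell, against 6.56% of genes whose regions had no call (odds ratio 2.65, adjusted p = 1.13e-38 by Fisher's exact test). Of genes with any gained region 12.7% rose, against 14.4% (odds ratio 0.864, adjusted p = 0.0434), and of those without a lost region besides 14.3% (0.992, 0.940). Within 5 kb these shares were 16.4% (adjusted p = 0.0644) and 18.1% (0.00794), against 13.5%. By type, the odds ratio for lost regions was 2.36 in normal skin, 2.79 in scar, 2.33 in hypertrophic scar and 2.34 in keloid, with adjusted p of at most 1.74e-17. For gained regions it was 1.23 in scar (adjusted p = 0.00392) and did not pass in normal skin (1.05, 0.483), hypertrophic scar (0.985, 0.871) or keloid (1.03, 0.795). Within 5 kb it passed in normal skin (1.43, 2.89e-07), scar (1.55, 0.000118) and keloid (1.43, 0.000570) but not in hypertrophic scar (1.26, 0.0644). Without genes that also had a lost region it was 1.15 in normal skin (0.0315), 1.45 in scar (1.85e-05), 1.05 in hypertrophic scar (0.579) and 1.28 in keloid (0.0307), and within 5 kb it passed in all 4 (adjusted p of at most 0.0362). Between unedited scar types and normal skin it was, for any gained region within 50 kb, 2.18 in scar, 2.18 in hypertrophic scar and 2.03 in keloid (adjusted p of at most 4.17e-18).

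In mouse lipofibroblasts, many transcripts differed between JUN and control libraries, listed by Ensembl identifier. ENSMUSG00000032081.3 stood at 26.3 ± 1.37 CPM in the JUN libraries and 0 in the controls (at least 621-fold higher, n = 2 per group). ENSMUSG00000054040.6 stood at 0.0439 against 59.3 ± 1.64 CPM, with 3 counts in the JUN libraries. The JUN libraries differed from the controls in 4145 (2222 higher and 1923 lower) of 16358 genes in lipofibroblasts, 4147 (1942 higher and 2205 lower) with total counts only, and in 6394 (3200 higher and 3194 lower) in reticular fibroblasts. The JUN effect itself differed between the populations in 3955 (2256 higher and 1699 lower) genes, and control lipofibroblasts differed from control reticular fibroblasts in 5328 (2583 higher and 2745 lower).

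The balance of higher and lower mouse transcripts in the reticular comparisons rested on the scaling, since TMM factors were 1.23 and 1.24 in the JUN and 0.795 and 0.806 in the control reticular libraries. In reticular fibroblasts, total counts only moved the median log2 fold change from 0.07 to 0.69 and called 7823 (5803 higher and 2020 lower) genes. For the difference of the JUN effect it moved the median log2 fold change from -0.06 to -0.77 and called 5230 (1157 higher and 4073 lower), and between control populations it moved the median log2 fold change from 0.04 to 0.41 and called 6205 (4206 higher and 1999 lower). In reticular fibroblasts, leaving out 1 library at a time, the count fell to 4181 without JUN reticular B and 4248 without JUN reticular A.

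In mouse ATAC data, more regions near leukocyte and lipid genes were lost than gained in the libraries titled JUN (n = 2 per group), by list tests that did not hold with an estimated correlation. Of macrophage and leukocyte marker regions 30 of 82 were lost (median -0.76) in lipofibroblasts, and 1 of 82 were gained and 43 lost (median -1.02) in reticular fibroblasts. Of lipid uptake and storage regions 15 of 121 were lost (median -0.21) in the former and 2 of 121 were gained and 34 lost (median -0.44) in the latter. Innate checkpoint ligands code for signals read by immune cells. Of their regions 9 of 49 were lost (median -0.37) in lipofibroblasts and 1 of 49 were gained and 20 lost (median -0.41) in reticular fibroblasts. Collagen and matrix regions passed upwards: 9 of 261 were gained and 1 lost (median 0.18) in lipofibroblasts and 18 of 261 were gained and 10 lost (median 0.15) in reticular fibroblasts. Reticular fibroblasts also had losses in hypoxia and glycolysis (7 of 144 were gained and 48 lost), the AP-1 family (6 of 111 were gained and 28 lost), stress and immediate early (9 of 198 were gained and 41 lost) and p53 target regions (1 of 80 were gained and 14 lost). Wnt signalling (16 of 136 were gained and 4 lost), contractile (11 of 127 were gained and 8 lost), pan-fibroblast (5 of 107 were gained and 6 lost) and skeletal muscle regions (4 of 26 were gained) passed upwards there. By camera the 4 lists in lipofibroblasts and no others passed, at adjusted p = 5.93e-16 to 0.00734. None held at adjusted p = 0.317 to 0.572 with an estimated correlation. Besides the lists in reticular fibroblasts none passed camera, which gave them adjusted p = 1.83e-17 to 0.0464. The calls were lost at adjusted p = 0.289 to 0.778 with an estimated correlation. Counts adjusted over the list alone in lipofibroblasts became 1 gained and 1 lost for collagens and matrix, 2 and 24 for lipid uptake and storage, 2 and 39 for leukocyte markers and 14 lost for innate checkpoint ligands. When adjusted over the list alone in reticular fibroblasts, 12 were gained and 34 lost for the AP-1 family, 14 and 10 for collagens and matrix, 13 and 52 for hypoxia and glycolysis, 1 and 21 for innate checkpoint ligands, 2 and 36 for lipid uptake and storage, 1 and 47 for leukocyte markers, 1 and 15 for p53 targets, 5 and 1 for skeletal muscle markers, 12 and 47 for stress and immediate early and 4 were lost for pan-fibroblast genes, with the others unchanged. 

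**Figure D4:**
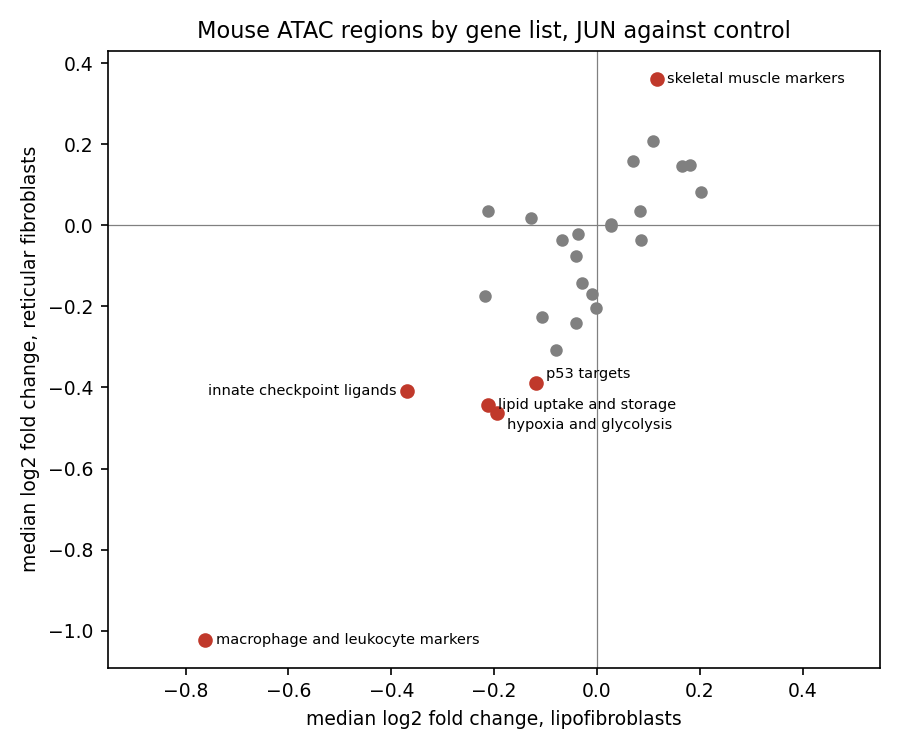
Median log2 fold change of the regions nearest the genes of each list, libraries titled JUN against control, in lipofibroblasts (x axis) and reticular fibroblasts (y axis), 1 point per list. Macrophage and leukocyte marker regions lie lowest in both, at -0.76 and -1.02.

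Mouse Cd36 had 8 tested regions, of which 1 was lost in lipofibroblasts (chromosome 5, 17363108 to 17364041, -1.07 ± 0.27) and 4 in reticular fibroblasts, the most at chromosome 5, 17360361 to 17360720 (-1.83 ± 0.37). Of the 8 regions of Jun, the one at its start (chromosome 4, 94718248 to 94720226) stood at -0.07 ± 0.41 and -0.38 ± 0.41, neither called, and chromosome 4, 94690081 to 94690716 was gained in reticular fibroblasts (1.44 ± 0.38). Among the largest losses were chromosome 14, 51575573 to 51576322 (-3.47 ± 0.33, 132 bp from Pnp2) in lipofibroblasts, Pnp2 being a purine nucleoside phosphorylase gene, and chromosome 14, 70253723 to 70254246 (-4.93 ± 0.33, 13758 bp from Pebp4) in reticular fibroblasts. Called were 9147 of 127450 regions in lipofibroblasts (2880 gained, 6267 lost) and 21176 in reticular fibroblasts (7226, 13950), against 5728 and 13865 with DESeq2. In reticular fibroblasts total counts only moved the median log2 fold change from -0.05 to 0.06 and called 25268 (13103 higher and 12165 lower), and only the groups compared gave 24491 (11795 higher and 12696 lower). With 1 library left out the count moved to 3454 without JUN lipofibroblast B and 4391 without JUN lipofibroblast A in lipofibroblasts, and to 10020 without JUN reticular B and 11167 without JUN reticular A in reticular fibroblasts.

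Between the populations, the change in the libraries titled JUN differed at 43 regions, 43 of them higher and 0 lower in lipofibroblasts by edgeR's test, and at 0 with DESeq2. At an unadjusted p under 0.05 edgeR's test had 10241 regions. Regions of stress and immediate early genes such as Fos and Egr1 were the list that passed camera, with a median difference of 0.28 (adjusted p = 0.0149, and adjusted p = 0.853 with an estimated correlation). Of its 198 regions 0 passed edgeR's test over all regions (19 higher and 3 lower at an unadjusted p under 0.05), and 6 passed adjusted over the list alone. With 1 library left out the count was 0 without JUN lipofibroblast A, 2 without JUN reticular B, 3 without JUN reticular A, 4 without JUN lipofibroblast B, 66 without control lipofibroblast B and 159 without control reticular A. Total counts gave 4, the replicate block 133 and the abundance-trended scaling 79.

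Between control lipofibroblasts and control reticular fibroblasts few regions differed (n = 2 per group). Regions of macrophage and leukocyte markers (3 of 82 were less open (median -0.55)), stress genes (2 of 198 were less open), the AP-1 family (3 of 111 were less open), innate checkpoint ligands (2 of 49 were less open), hypoxia and glycolysis (3 of 144 were less open) and p53 targets (1 of 80 were less open) passed camera downwards. Collagen (2 of 261 were more open and 1 less open) and Wnt signalling regions (2 of 136 were more open) passed upwards. Pan-fibroblast, HOX and reticular fibroblast regions passed upwards and lipid regions downwards with 0 members called over all regions by edgeR's test. At an unadjusted p under 0.05 they had 13 higher and 2 lower (pan-fibroblast), 7 higher and 3 lower (HOX), 13 higher and 3 lower (reticular) and 4 higher and 28 lower (lipid). With members adjusted over the list alone, 1 were more open and 9 less open for innate checkpoint ligands, 3 and 1 for reticular fibroblast genes, 2 and 1 for Wnt signalling, 9 were less open for the AP-1 family, 4 were less open for hypoxia and glycolysis, 14 were less open for lipid uptake and storage, 22 were less open for leukocyte markers and 9 were less open for stress and immediate early, with the others unchanged. Camera passed these lists and no others, at adjusted p = 3.70e-10 to 0.0289. None of them held at adjusted p = 0.17 to 0.605 with an estimated correlation. The libraries differed at 734 regions (129 higher and 605 lower), and at 2877 (812 higher and 2065 lower) with the abundance-trended scaling. Total counts only gave 727 (354 higher and 373 lower), without the excess of lower regions. The count rested on single libraries and the tool: it was 0 without control reticular B, 329 without control lipofibroblast B, 461 without control lipofibroblast A and 3909 without control reticular A, 6 with only the groups compared and 3 with DESeq2.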

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

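Tests on the JUN transcript, on marker genes and the donor, and of the labelled KO effect between skin types were chosen only after the result was seen. Those on leukocytes and depth were set before.

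JUN RNA was not lower over the 4 types in libraries labelled KO (-0.07 ± 0.25), though JUN was the edited gene. Labels exchanged in some types would give correlations of the labelled KO effect below 0, but the lowest of 6 was 0.453, which argues against it. Cells mostly unedited and like the unedited cultures would leave few large changes. The same 43 genes were called with a log2 fold change below -2 in all 4 types, which argues against that. An edit that leaves the transcript may apply, since JUN RNA fell in 1 of 4 types, as may unedited cells that differ otherwise. Protein or reads over the edited site are needed to tell. No biological explanation was tested.

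Leukocyte marker regions were less open in mouse libraries titled JUN, with medians of -0.76 in lipofibroblasts and -1.02 in reticular fibroblasts. The control libraries were shallower. With JUN libraries thinned to the controls' mean, 5.19 M reads, medians were -0.83 and -1.0. Thinning keeps each region's expected share of reads, so it cannot test depth. Fewer sorted leukocytes could do this as well as a change within fibroblasts. Without counts of cell types these cannot be told apart. By replicate difference the list ranked 6 of 27 in 1 control group and 24 in the other. That decides nothing, since a share lower in both JUN replicates need not vary in controls. No biological explanation was tested.

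With replicates summed, CD36 in unedited hypertrophic scar cells stood at 259 CPM, against 2.35 to 7.61 in the other 3 types, and 30.8 against 0.226 to 0.847 CPM in the labelled KO libraries. Adipocytes, endothelial cells or macrophages would bring abundant markers, but the highest median of 3 was 0.685 CPM (FABP4 0.487, PECAM1 0.685, LYZ 4.57). This argues against them unless shared isoform reads were lost. The donor or culture may account for it as well as the scar type, since 1 donor stands for each type and the mean over its libraries was 34.2-fold the next, and these cannot be told apart. The labelled KO effect on CD36 was not shown to differ in hypertrophic scar from normal skin (adjusted p = 0.805), scar (0.979) or keloid (0.194). No biological explanation was tested.

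Further values stood apart from the rest of their group, 8 with the CD36 levels among 105 groups of 4 or 8 values, where about 1 in 20 does so by chance. The labelled KO log2 fold change of NEFM was 8.91 in keloid and 3.78 to 4.60 in the other types, and that of IGSF10 -4.50 in hypertrophic scar and -7.11 to -6.75 elsewhere. Both keloid fits stand against 0 counts, where the data give only bounds of at least 5.43 and at most -3.37, so these 2 may not stand apart. JUND changed by -1.26 in normal skin against -0.49 to -0.42 and CDH2 by 1.15 in scar against 2.05 to 2.17. Mouse RNA JUN lipofibroblast A held 32.3 M reads against 35.0 to 35.4, and mouse ATAC control reticular B 8.47 against 3.87 to 4.38.

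The labelled KO effect differed between hypertrophic scar and normal skin at 890 genes, scar at 678 and keloid at 781, by edgeR's test. In human ATAC it differed at 2653, 2465 and 11578 regions. The JUN effect in mice differed between the populations at 3955 genes and 43 regions.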

How the results depend on the processing

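Splits of the human RNA libraries and the abundance-trended scaling were tests chosen only after the result was seen. The other alternatives were set before the data were examined.

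With DESeq2's size factors (RLE), no filter or a mean of 10 counts all 24 counts of the comparisons stayed within 1.5-fold, as did 23 with total counts only, 22 with the abundance-trended scaling, 20 with DESeq2 and 19 of the 20 run with only the groups compared. Mouse ATAC counts moved with DESeq2, from 9147 to 5728 in lipofibroblasts and from 21176 to 13865 in reticular fibroblasts, and the cause was not tested. The count for the difference of the JUN effect, 43 regions, became 4 with total counts, 79 with the trended scaling and 0 with DESeq2. Between control populations 734 regions became 2877 with the trended scaling, 6 with only the groups compared and 3 with DESeq2.

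With the replicate block, 20 of 22 counts stayed within 1.5-fold (mouse RNA in lipofibroblasts 3806 against 4145), while the mouse ATAC difference of the JUN effect became 133 and the control comparison 1384. Letters were not taken to pair libraries: differences between A and B correlated above 0.1 in 15 of 28 pairs of human RNA groups, 1 of 6 in mouse ATAC and 0 in the other tables.

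Over the 4 types, 16 libraries as separate samples raised the counts to 5032 genes and 90582 regions, and a fit without the skin type term lowered them to 1269 and 15. Without 1 skin type they lay at 1074 to 1715 genes and 26540 to 44597 regions. Of 8 splits of the 8 summed RNA libraries that part every donor pair, 1 gave as many genes, the real one with 2597, and the highest other gave 0. For ATAC 1 of 8 splits gave as many, with 53335 regions in the real one and 0 in the highest other. These are too few splits for a share under 0.05.

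Leave-out fits keep a lone sample in a group and assume that it varies like the other groups. Their counts for the labelled KO effect in RNA were 1672 to 2115 in scar and 1703 to 2390 in keloid, and against normal skin 504 to 730 in scar, 1569 to 2315 in hypertrophic scar and 1711 to 2506 in keloid. In human ATAC they were 28139 to 40105 in normal skin, 19667 to 30718 in scar, 15957 to 22747 in hypertrophic scar and 42384 to 44327 in keloid, and against normal skin 14090 to 18359 in scar and 36056 to 44682 in keloid. In mouse RNA they were 4181 to 6260 in reticular fibroblasts. In mouse ATAC they were 3454 to 6796 in lipofibroblasts, 10020 to 21774 in reticular fibroblasts, 0 to 159 for the difference of the JUN effect and 0 to 3909 between control populations.

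Of lists over the 4 types, 6 passed camera, 0 with an estimated correlation and 11 with fry. Within 5 kb the link of gained regions to RNA turned, at 16.4% of genes rising, and the cause was not tested. JUN in scar passed without a filter alone (adjusted p = 0.0292, range 0.0292 to 0.958), and JUN in keloid against normal skin without a filter (0.00351) and with the block (0.0376, range 0.00351 to 0.990). Of 4514 alternative values of named genes 4249 kept their call, 261 lost it, 4 gained one and 0 turned. With the mouse ATAC JUN libraries thinned to the mean depth of the controls, 6910 regions were called in lipofibroblasts (2014 gained, 4896 lost) and 17806 in reticular fibroblasts (7548, 10258). A motif window and alternatives for normalized values were not run.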

Other observations

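Ranges over libraries, neighbouring regions and HBB RNA were tests chosen only after the result was seen. The 2 HBB regions came from a planned comparison.

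In libraries labelled JUN KO, ATAC reads over the beta-globin gene HBB, whose sequences are used in gene transfer vectors, were higher in 4 of 4 skin types. The region at chromosome 11, 5246049 to 5247414 ranged from 8.20 to 373 CPM in the labelled KO and 0.484 to 15.7 in the unedited libraries (3.44 ± 0.17, adjusted p = 7.98e-09), and that at chromosome 11, 5247625 to 5247902 from 0.257 to 22.3 and 0.0968 to 1.05 CPM (3.45 ± 0.38). Of the neighbouring regions those nearest HBD (-0.61 ± 0.32), HBBP1 (0.55 ± 0.64) and HBG1 (-0.83 ± 0.55) had no call, and that nearest HBG2 was lost (-1.54 ± 0.47, adjusted p = 0.0256). HBB RNA held 0 to 13 counts per library, 37 in all 16.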
